A study of Mus musculus with 12 samples.

How the data were processed

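Total RNA from 12 embryonic mouse lung samples, 4 per genotype, was extracted with Trizol, treated with DNase, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The deposited scanner table holds 1 linear intensity per probe and array with no normalization between arrays, per the file headers, and beside it a deposited detection p-value that sets each probe against the negative controls of its array. The authors' deposited series matrix holds log2 values. Their ranks match the scanner intensities of the same array, and they differ from quantile-normalized log2 intensities by a median of 0.00386, so they are log2, not centred per gene and run in the direction of intensity. Their medians lie between 6.91 and 6.93 on the 12 arrays. The software and version used by the authors are not given in the sources used here.

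From the intensities, background was fitted by the normexp model from the detection p-values, since the negative control probes were not used here, with an offset of 16, followed by quantile normalization on the log2 scale (nec and normalizeQuantiles in limma 3.58.1, R 4.3.3). Probes had to have a detection p under 0.01 on at least 4 of the 12 arrays, which 11841 of 25697 did. Raw upper quartiles ran from 226.6 to 390.1 and the 5th percentile of raw intensity from 84.79 to 105.4. Of the probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were unlisted and stayed unnamed. Symbols were looked up through gene identifiers in a RefSeq table of assembly GRCm38.p6, which held 23962 of them, and 0 symbols changed. No coordinates are given, because the array files name no build, and that assembly served only for names, chromosomes and neighbouring genes. Where several probes of a gene passed, the probe with the highest mean log2 value over all 12 arrays stood for it (2096 genes had several), which left 8311 genes.

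The 3 group means were fitted in 1 linear model over all 12 arrays with lmFit and eBayes, leaving 9 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over genes, for double mutant against control, double mutant against 1 Mek1 allele, and 1 Mek1 allele against control. A total of 28 gene lists for lung cell types, other tissues and pathways was set, of which 24 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01 and adjusted over the 72 tests. The lists of liver and plasma proteins, thymus and T cells, neural cells and neuroendocrine cells had too few members for a test. Spag6 was read through its current symbol Spag6l. Fam183b of the ciliated list was at first matched in error to another gene. The match was removed after values had been seen, which left 8 measured members and the list still past the threshold in the same comparisons. Shared controls were looked at with 100 simulations of unchanged groups and with the 6 ways of giving each mutant group its own 2 controls.

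Named genes followed a rule. Map2k1, Map2k2 and Twist2 are always given. Among genes past the threshold whose 4 values in 1 group all lie beyond the 4 of the other, the 10 largest rises and 10 largest falls were taken for double mutant against control, 8 and 8 against 1 Mek1 allele, and 6 and 6 for 1 Mek1 allele against control, passing over predicted-gene symbols. Up to 3 members of each list past the threshold with the smallest p were added. Other list members named in the text are given with their values to describe their list. Apart from that correction, the groups, tests, lists, naming rule and all alternatives except 3 were set before the data were examined.

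The alternatives were other background and scaling choices, the authors' log2 values, other filters and probe rules, stricter thresholds, array weights, another variance model, the replicate number as a block, Y-linked signal as a covariate, only the arrays compared, other list tests, and leaving out each array. Added after seeing the data were array brightness or array background as a covariate and leaving out the 2 brightest arrays. No 2 arrays were duplicates: within groups the correlation of log2 values ran from 0.981 to 0.993.

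The procedure was tested on simulated data with the real means and spreads of the 8311 genes, 200 of them changed in double mutants against controls. It recovered 38.8% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 100% of changes of 2, with 9 false calls among 159. A list shift of -0.3 was recovered in 20 of 20 simulations, with 5 false calls in 1380 unchanged list tests. These simulated genes varied independently, so the list figure says nothing about correlated members.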

Results

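The experiment measured messenger RNA in whole embryonic mouse lungs on Illumina bead arrays, which carry 25697 gene-expression probes. Lungs came from E15.5 embryos, with the same background strain for every group per the labels. MEK1 and MEK2, encoded by Map2k1 and Map2k2, are the kinases that activate ERK in the MAPK pathway. Every embryo carried Dermo1-Cre, a recombinase expressed from the Twist2 locus in embryonic mesenchyme. The control group carried this driver alone. In the second group Map2k2 was inactivated in every cell and 1 floxed and 1 intact Map2k1 allele were present, so that recombined mesenchyme kept 1 Mek1 allele (called here 1 Mek1 allele). In the third group both Map2k1 alleles were floxed and Map2k2 was again inactivated in every cell (called here double mutant). Each group had 4 specimens, giving 12 arrays. The labels do not say whether a specimen was a single lung or a pool, so the tests measure the spread between these specimens. Between 10467 and 11878 probes per array were above background (detection p under 0.01), and 8311 named genes entered the tests. The number of arrays limits the precision. Values are log2 intensities as mean ± SD, and changes are log2 differences ± SE with limma's adjusted p.

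The genotype was read first from the targeted genes. Map2k2 measured 11.59 ± 0.08 in controls (n = 4), 10.58 ± 0.15 with 1 Mek1 allele (n = 4) and 10.85 ± 0.24 in double mutants (n = 4). It fell by 1.02 ± 0.12 with 1 Mek1 allele (limma adjusted p = 0.00209) and by 0.74 ± 0.12 in double mutants (limma adjusted p = 0.00791), and all 8 mutant arrays lay below all 4 controls. A second, dimmer Map2k2 probe was above background on 4 of 4 control arrays and on 1 of the 8 mutant arrays. Whether either probe lies in the deleted part of Map2k2 is not given in the sources used here, so the remaining signal of the brighter probe has no reading as residual transcript. The Map2k1 probe was above background on 0 of 12 arrays and checks nothing about the Mek1 deletion. Twist2 measured 7.28 ± 0.26 in controls, 7.36 ± 0.20 with 1 Mek1 allele and 7.37 ± 0.23 in double mutants, and passed the threshold in no comparison.

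The comparison of double mutants with controls asked what the loss of Mek2 in every cell and of Mek1 in recombined mesenchyme changed in the lung. Some genes of airway epithelium rose in double mutants. Cyp2f2, a cytochrome P450 of club cells, rose 2.56-fold (log2 1.35 ± 0.20, limma adjusted p = 0.00406), and Cbr2, a carbonyl reductase also made by club cells, rose 2.72-fold (log2 1.44 ± 0.20, limma adjusted p = 0.00305). Of genes of motile cilia, 4 rose, among them the tektin Tekt1 2.03-fold, the axonemal gene Spag6l 2.25-fold and Mcidas, a regulator of multiciliated cell formation, by 1.06 ± 0.22 on the log2 scale, Spag6l being above background on 2 and Mcidas on 3 of 4 control arrays. Haptoglobin, Hp, which binds free haemoglobin, rose 3.06-fold (log2 1.61 ± 0.26), and histidine decarboxylase, Hdc, 2.81-fold (log2 1.49 ± 0.23). The lymphoid chemokine Ccl21a fell by 1.07 ± 0.14, and Slc4a1, the anion exchanger of red cells, fell by 1.03 ± 0.19.

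Other large changes in double mutants were in genes that belong to none of the lists, and a common role was not tested. Hebp1, a haem-binding protein, rose 6.16-fold (log2 2.62 ± 0.22, limma adjusted p = 4.6e-05) and the aldo-keto reductase Akr1c19 rose 5.4-fold (log2 2.43 ± 0.13, limma adjusted p = 1.89e-07). Nudt6 was not above background on any control array and was at least 2.86-fold higher in double mutants. Ooep rose 3.31-fold, the sialic acid enzyme Cmas 2.94-fold, the histone gene H4c9 2.81-fold and Katnal1, above background on 2 of 4 control arrays, 2.58-fold. Timmdc1, which takes part in assembly of mitochondrial complex I, fell by 3.50 ± 0.16, the most of the named genes (limma adjusted p = 7.7e-08). The centromere gene Itgb3bp fell by 2.33 ± 0.41, Cdkal1 by 1.56 ± 0.27 and Map2k6, a kinase of the p38 pathway, by 1.51 ± 0.32, where 2 other Map2k6 probes gave -0.92 and -0.98. With 1 Mek1 allele Map2k6 also lay below controls, at -0.95 without passing (limma adjusted p = 0.168), and its other probes gave -0.79 and -1.21. Prm1, Trim10, Gbp2b and Msantd1 were above background on 0 of the 4 double mutant arrays and were at least 1.88-fold, 2.42-fold, 1.81-fold and 1.22-fold lower there. Such bounds set the brighter group's mean against the lowest signal above background, or the dim probe's own signal where that was higher, on each array of the other group. Ccl21b and Ccl21c also fell, by 1.04 ± 0.18 and 1.20 ± 0.20, but these genes and Ccl21a are near-identical copies, as are the histone genes, so which copy a probe reports is uncertain.

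In all, 251 of 8311 genes passed the threshold in double mutants against controls, 158 higher and 93 lower, and 152 of them differed by at least 1.5-fold. In 1139 genes, 13.7% of those tested, the 4 double mutant values lay wholly outside the 4 control values, where chance gives 2.86%. The count was 109, 116 and 147 without control replicate 2, 3 or 4, and 153, 148 and 118 without double mutant replicate 2, 3 or 4. Control replicates 2 and 3 were the brightest arrays, with raw upper quartiles of 390 and 388 against 227 to 306 on the other 10, and leaving out both left 10 genes. Of 50 named genes past the threshold here, 33 passed under every one of the 12 single omissions, and 17 did not: Tie1 passed in 0 of 12, Emp2 in 3, Bbc3 and Muc1 in 5, Insm1, Trf and Riiad1 in 6, Abca9, Krt19, Map2k6, Msantd1 and Tyms in 7, Mcidas in 8, Ccne2, Rrm2 and Upk3b in 10 and Rspo1 in 11.

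Of the 24 gene lists with enough measured members, 4 differed between double mutants and controls (camera with a preset correlation, adjusted over 72 tests). The ciliated airway list was higher, with a median change of 1.04 and adjusted p = 0.00054, and 4 of its 8 measured members rose: Tekt1, Spag6l, Mcidas and the radial spoke gene Rsph1 (log2 1.25, limma adjusted p = 0.0278). Adjusted over the list alone, 5 passed. Foxj1, the transcription factor of motile ciliogenesis, changed by 0.11 (limma adjusted p = 0.78), below the threshold. The hypoxia and glycolysis list was higher, with a median of 0.33 and adjusted p = 0.003. Of its 11 measured members 0 passed singly, over all genes or over the list alone, though all 11 had positive changes, among them P4ha1 at 0.46 and Ndrg1 at 0.41. The secretory and basal airway list was higher, with a median of 0.28 and adjusted p = 0.0297. Of its 7 measured members 1, Cyp2f2, rose over all genes and 2 over the list alone, and Sox2 changed by 0.58 (limma adjusted p = 0.051). The cell proliferation list was lower, with a median of -0.11 and adjusted p = 0.0174. Of its 20 measured members 3 fell: the S-phase cyclin Ccne2 by 0.53 ± 0.10 and the nucleotide synthesis genes Tyms by 0.43 ± 0.09 and Rrm2 by 0.61 ± 0.13, and the same number passed over the list alone. A second Rrm2 probe gave -0.20, and other Tyms probes -0.72, -0.38 and -0.20. All 4 calls were lost with an estimated correlation, where adjusted p = 0.224 for each of these lists. The number of lists was 2 without control replicate 1, 8 without control replicate 2, and 7 without double mutant replicate 1 or 1 Mek1 allele replicate 3.

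**Figure D1:**
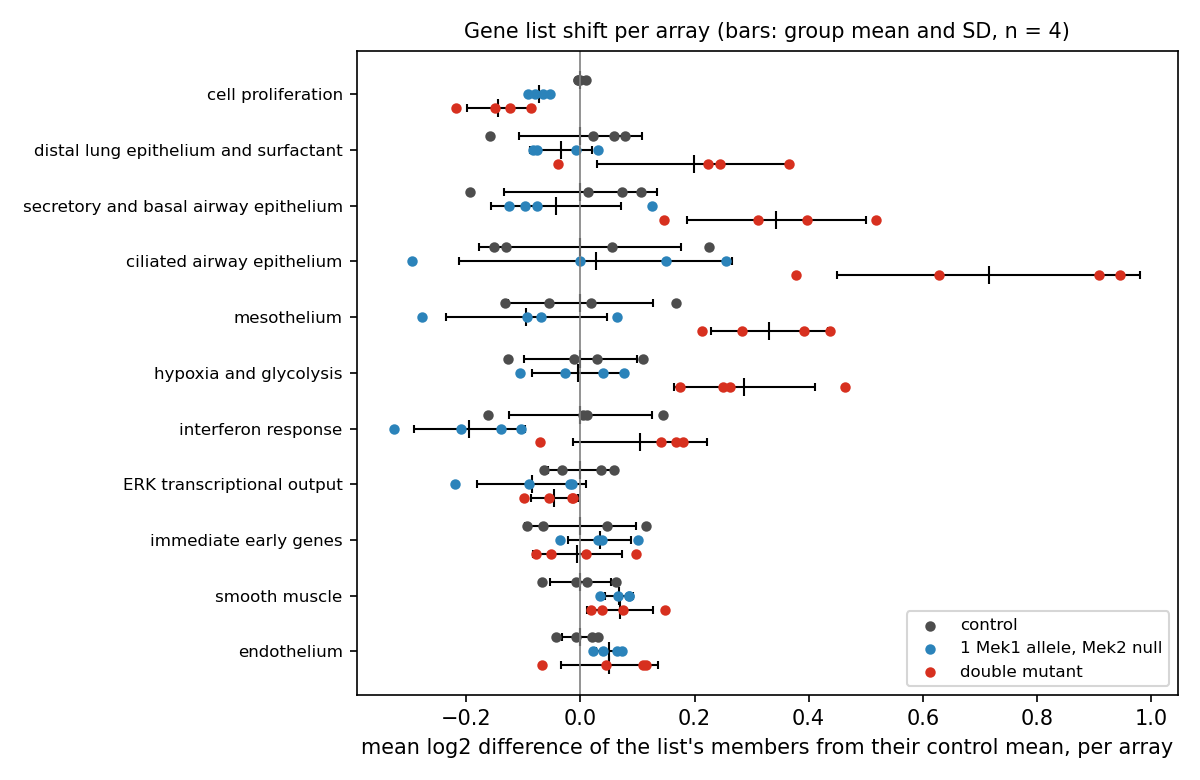
Mean log2 difference of each gene list's measured members from their control mean on each array, by group, with bars for the group mean and SD (n = 4). The 4 double mutant arrays lie above all controls for the ciliated list, at 0.38 to 0.94, and below all controls for the proliferation list, at -0.22 to -0.09.

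Genes that report ERK activity did not shift as a list in double mutants (12 of 21 members measured, median -0.09, camera adjusted p = 0.547). The RNA came from whole lung, including cells in which Mek1 was not recombined, and the Mek1 deletion could not be checked. The list therefore does not show that ERK activity was kept in recombined mesenchyme. Members went opposite ways: Egr1 fell by 0.74 ± 0.13 (limma adjusted p = 0.0112) and Ier3 rose by 0.92 ± 0.16 (limma adjusted p = 0.00889). Dusp6 changed by -0.08, Spry4 by -0.05 and Etv5 by 0.02, none past the threshold. The immediate early list, which shares Egr1, had a median of -0.11 (adjusted p = 0.985). In the list of p53 targets and cell cycle inhibitors the cyclin-dependent kinase inhibitor Cdkn1a rose by 0.75 ± 0.13 and the apoptosis gene Bbc3 by 0.51 ± 0.12, the list having adjusted p = 0.153 with camera and adjusted p = 0.0124 with fry. Fry sets a list against no change, camera against the other genes. With camera and an estimated correlation this list had adjusted p = 0.331, and it passed in 1 of 29 settings. A dim second Bbc3 probe gave -0.04, and other Cdkn1a probes 0.49 and 0.54. The stress genes Ddit4 and Vldlr rose by 0.79 ± 0.12 and 0.55 ± 0.10, in a list with adjusted p = 0.404.

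Markers of other cells in the dissected lung passed singly against controls, but their lists did not pass under camera. Under fry the mesothelial list (adjusted p = 0.0134) and the alveolar type 1 list (adjusted p = 0.0194) did. With camera and an estimated correlation they had adjusted p = 0.224 and 0.244. The mesothelial markers Upk3b, Rspo1 and Krt19 rose by 0.65 ± 0.13, 0.95 ± 0.19 and 0.69 ± 0.15, 3 of 6 measured members (adjusted p = 0.0562 for the list). Of the rest, Wt1 changed by 0.08, Aldh1a2 by 0.06 and Upk1b by -0.44, none past the threshold. Emp2 rose in the alveolar type 1 list (0.52 ± 0.13, list adjusted p = 0.0555), Muc1 in the distal epithelium and surfactant list (0.57 ± 0.13, list adjusted p = 0.0773), the complement gene C1qc in the macrophage list (0.81 ± 0.13, list adjusted p = 0.0562) and Tie1 in the endothelial list (0.34 ± 0.09, list adjusted p = 0.547). Transferrin, Trf, rose by 0.82 ± 0.19. Insm1, a neuroendocrine gene, passed the threshold (limma adjusted p = 0.0389) but was above background on 1 of 4 control arrays and 4 of 4 double mutant arrays, so its size is not given. The lists of both had too few measured members for a test. The erythroid list moved both ways (adjusted p = 0.547), with Slc4a1 lower and the embryonic globin Hbb-bh1 at 1.07 (limma adjusted p = 0.0539). No list past the threshold was found under camera among mesenchyme regulators (adjusted p = 0.845), the Hedgehog pathway (0.864), Wnt targets (0.845), smooth muscle (0.626), cartilage (0.651), extracellular matrix (0.372), YAP and SRF targets (0.547), interferon response (0.726), skeletal muscle (0.435) or cardiac muscle (0.153), all as adjusted p.

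The comparison of double mutants with the 1 Mek1 allele group asked what loss of the last Mek1 allele in recombined mesenchyme changed on a Mek2-null background. That loss itself could not be checked. Some of the airway genes named above passed here too. Cyp2f2 rose 2.45-fold (log2 1.29 ± 0.20, limma adjusted p = 0.0275), Cbr2 2.17-fold, Spag6l 2.25-fold and Tekt1 1.88-fold. Mcidas (limma adjusted p = 0.052) and Rsph1 at 1.30 (limma adjusted p = 0.0589) stayed short of the threshold. With 1 Mek1 allele Spag6l and Rspo1 were above background on 2 of 4 arrays, and Mcidas on 1. Other rises were in Cyp2s1 (2.02-fold), the secreted Wnt agonist Rspo1 (1.95-fold), Wfdc1 (1.94-fold), Riiad1 (1.93-fold) and Vldlr (1.49-fold). Sgsm1, not above background on any array with 1 Mek1 allele, was at least 1.28-fold higher, though it passed against controls in neither mutant group. Timmdc1 fell by 2.55 ± 0.16 (limma adjusted p = 4.44e-06), Slc4a1 by 0.99 ± 0.19, Angptl4 by 0.84 ± 0.15 and Asap2 by 0.67 ± 0.14. Trim10 was at least 2.05-fold lower. Ccl21a, Ccl21b and Ccl21c fell by 0.91 ± 0.14, 1.04 ± 0.18 and 1.14 ± 0.20. A second Asap2 probe gave -0.02.

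In this comparison 45 genes passed, 34 higher and 11 lower, from 958 with unadjusted p under 0.05, and 75.6% of calls were higher (65.2% with upper-quartile scaling). The count was 2, 3 and 4 without double mutant replicate 2, double mutant replicate 4 or 1 Mek1 allele replicate 4, 7 and 12 without control replicate 3 or 2, 15 without double mutant replicate 3 or 1 Mek1 allele replicate 3, 17 without 1 Mek1 allele replicate 1, 29 without double mutant replicate 1, and 8 without the 2 brightest arrays. It was 1 when only these 8 arrays were fitted and 2 with Y-linked signal as a covariate. Of 18 named genes past the threshold, only Timmdc1 passed under every one of the 12 single omissions.

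Lists higher in double mutants than with 1 Mek1 allele numbered 6, and 0 were lower. The ciliated list had a median of 1.002 (adjusted p = 0.000457), with 2 of 8 members past the threshold and 5 over the list alone. The hypoxia and glycolysis list had a median of 0.35 (adjusted p = 0.000668), with 0 of 11 members past it and 7 over the list alone, among them Ndrg1 at 0.51. The mesothelial list had a median of 0.43 and the secretory and basal list one of 0.58 (adjusted p = 0.00217 for both), with 1 member each past the threshold, Rspo1 and Cyp2f2, and over the list alone 3 of 6 higher and, for the airway list, 5 of 7 higher and 1 lower. The interferon list had a median of 0.30 (adjusted p = 0.0183), with 0 of 7 past it in either way. From the control mean, the interferon list lay at -0.19 with 1 Mek1 allele and 0.10 in double mutants, neither past the threshold against controls. The distal epithelium list had a median of 0.16 (adjusted p = 0.0492), with 0 of 14 past it and 1 over the list alone. The distal epithelium list passed in 15 of 29 settings. It lay at -0.04 in double mutant replicate 1 and at 0.22 to 0.37 in the other double mutant replicates. With an estimated correlation all 6 calls were lost: adjusted p = 0.196 for the mesothelial and secretory lists, adjusted p = 0.224 for the ciliated, hypoxia and interferon lists, and adjusted p = 0.363 for the distal epithelium list. Without double mutant replicate 1, 10 lists passed.

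**Figure D2:**
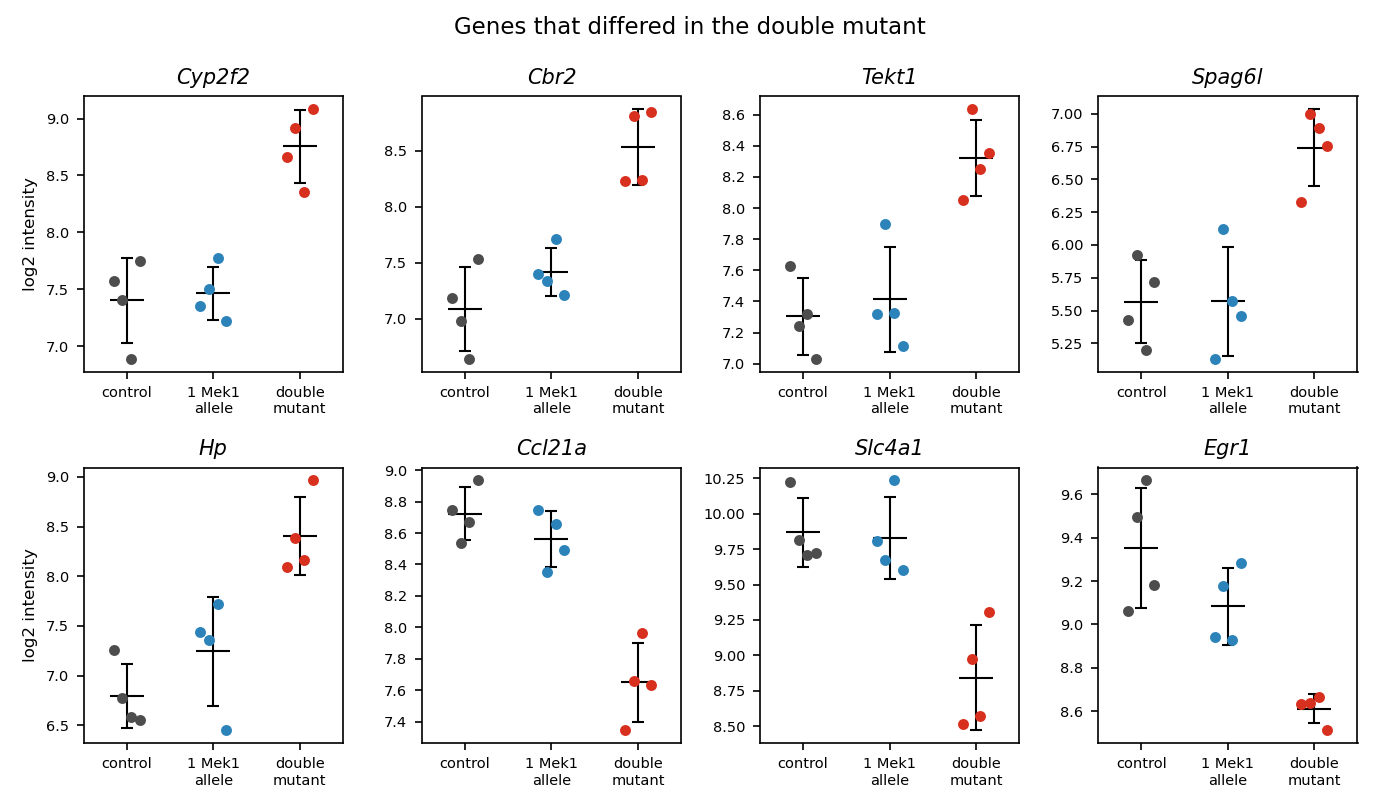
Log2 intensity of 8 genes on each array (y axis, not starting at 0) by group (x axis), with bars for the group mean and SD (n = 4). Cyp2f2, Cbr2, Tekt1, Spag6l and Hp are higher in double mutants, and Ccl21a, Slc4a1 and Egr1 lower, than in every control array.

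The comparison of the 1 Mek1 allele group with controls asked what changed while 1 Mek1 allele remained. Hebp1 rose 7.31-fold (log2 2.87 ± 0.22, limma adjusted p = 2.05e-05), Akr1c19 6.26-fold (log2 2.65 ± 0.13, limma adjusted p = 1.28e-07), Cmas 3.29-fold and H4c9 3.29-fold. Ero1b, an oxidase of the endoplasmic reticulum, passed the threshold (limma adjusted p = 0.0184) but was above background on 1 of 4 control arrays, so its size is not given. Nudt6 was at least 2.31-fold higher. Itgb3bp fell by 2.04 ± 0.41, Cdkal1 by 1.54 ± 0.27, Map2k2 by 1.02 ± 0.12, Timmdc1 by 0.95 ± 0.16 and Abca9, above background on 2 of 4 arrays with 1 Mek1 allele, by 0.91 ± 0.19. Prm1 was at least 1.76-fold lower. The other 2 Abca9 probes gave -0.17 and -0.23.

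Here 53 genes passed, 25 higher and 28 lower, from 1364 with unadjusted p under 0.05, and 47.2% of calls were higher (59.2% with upper-quartile scaling). No list passed under camera, and fry also found 0. The proliferation list, with camera adjusted p = 0.356, still lay at -0.09 to -0.05 on the arrays with 1 Mek1 allele, below all controls at -0.005 to 0.009. Its mean was -0.07 with 1 Mek1 allele and -0.14 in double mutants. With 1 Mek1 allele against controls it passed in 0 of 29 settings. Double mutants against 1 Mek1 allele also stayed short of the threshold (camera adjusted p = 0.0562). Whether its fall was particular to double mutants is therefore not settled. Single list members all stayed short of the threshold, Dusp6 at -0.35 (limma adjusted p = 0.0857) and the ciliated list at a median of -0.02 (camera adjusted p = 0.802). The skeletal muscle list, a marker set of other tissue, had a median of 0.48 (adjusted p = 0.0771). The count of genes was 15 without control replicate 2 or 3, 20 without 1 Mek1 allele replicate 2, 23 and 24 without control replicate 1 or 4, 5 without the 2 brightest arrays and 23 with only these 8 arrays fitted. Of 13 named genes past the threshold, 7 passed under every single omission: Akr1c19, Cmas, H4c9, Hebp1, Map2k2, Nudt6 and Prm1.

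**Figure D3:**
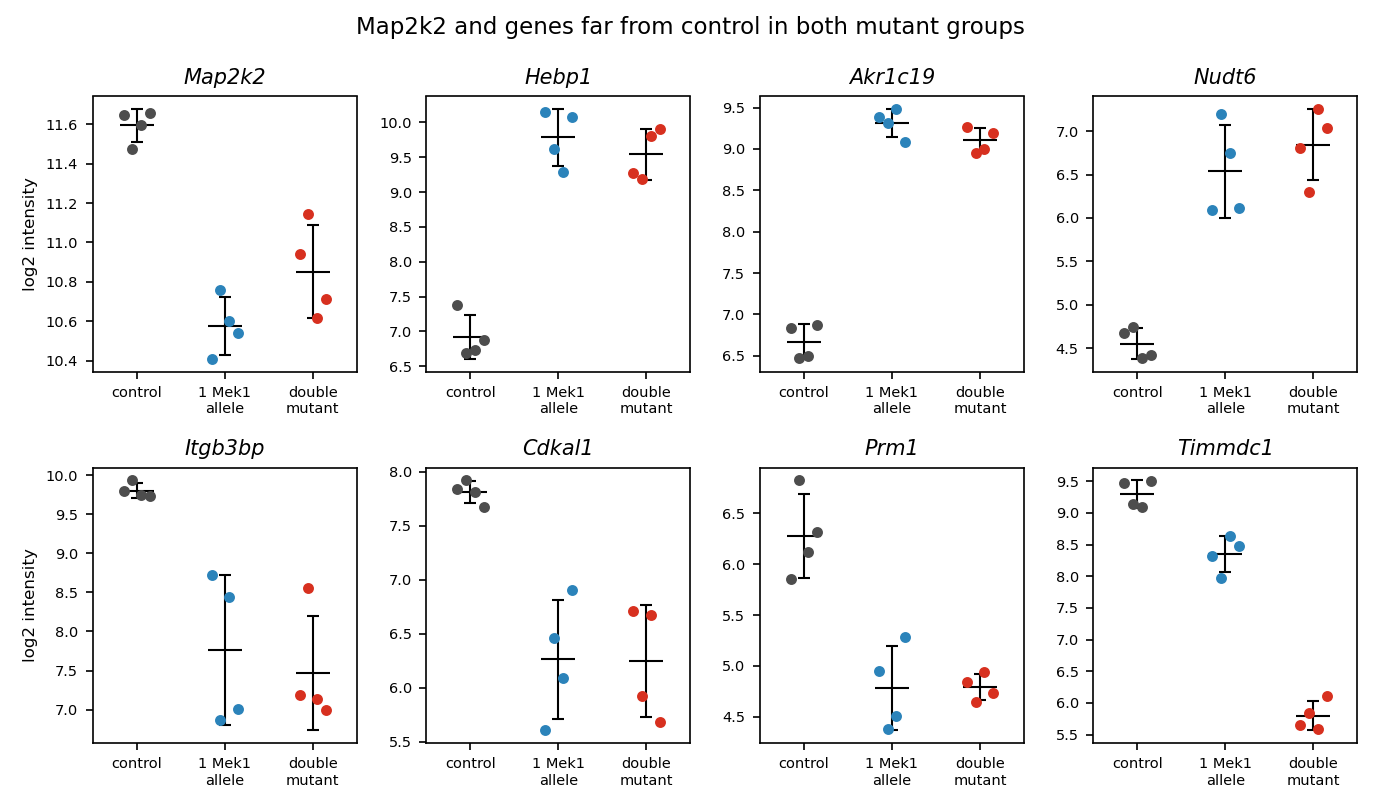
Log2 intensity of Map2k2 and 7 other genes on each array (y axis, not starting at 0) by group (x axis), with bars for the group mean and SD (n = 4). All 8 mutant arrays lie on 1 side of all 4 controls for each gene, and Timmdc1 is at 9.30 in controls, 8.35 with 1 Mek1 allele and 5.80 in double mutants.

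The mutant groups shared many of the largest changes. In both against controls, 36 genes passed in the same direction, 21 higher and 15 lower, and 0 passed in opposite directions. Independent lists of these sizes would share 0.475 higher and 0.313 lower, and simulated unchanged groups set against the same controls shared 0.01 higher and 0 lower. Neither figure tells how much of the overlap comes from the shared controls. Independent lists leave the shared arrays out, and unchanged groups have few genes past the threshold to share. The 36 became 19, 13, 14 and 19 without control replicate 1, 2, 3 or 4, 17 without 1 Mek1 allele replicate 2, 20 and 21 without double mutant replicate 3 or 4, 8 and 9 with array brightness or array background as a covariate, and 3 without the 2 brightest arrays. Hebp1, Akr1c19, Nudt6, Ooep, Cmas and H4c9 were among the 21, and Itgb3bp, Cdkal1, Prm1, Map2k2 and Timmdc1 among the 15. Only Timmdc1 of these also differed between the mutant groups in the direction that extends its fall. Across genes, which are not independent replicates, the log2 changes of the mutant groups correlated with r = 0.644, against 0.499 in simulated unchanged groups with shared controls and 0.39 when the controls were split between the groups. Their covariance was 0.0403, against 0.0134 simulated, a difference of 0.0269. With the controls split, the mean covariance was 0.0287. The split groups share no control array, so the simulated figures with shared controls are no yardstick for the split ones.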

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

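Tests of neighbouring genes, of related gene families and of the counts per chromosome were chosen only after the results they bear on were seen. The other tests of this part had their outcomes written beforehand, when the ciliated list was already known to be higher. Those for the ciliated list were written for a wider pattern of airway, hypoxia and proliferation lists, and were narrowed to the ciliated list after their results were seen.

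Each group of 4 arrays was searched for an array standing apart, by Dixon's gap test for 4 values. This picked 13 of 243 groups looked at, and chance picks about 1 in 20. In double mutants Asap2 was 6.02 in replicate 4 against 6.35 to 6.39 in the others, Ccl21c 6.91 in replicate 3 against 6.15 to 6.25, Itgb3bp 8.56 in replicate 2 against 6.99 to 7.19 and Vldlr 10.1 in replicate 2 against 9.97 to 10. With 1 Mek1 allele Cyp2s1 was 6.18 in replicate 4 against 6.83 to 6.92, Muc1 9.35 in replicate 4 against 9.88 to 9.96, Sgsm1 5.21 in replicate 2 against 4.62 to 4.71 and Tie1 8.16 in replicate 2 against 8.01 to 8.03. Ddit4 was 9.13 in control replicate 2 against 8.98 to 8.99. Among list means in double mutants, cartilage was -0.0324 in replicate 3 against -0.153 to -0.136, extracellular matrix -0.114 in replicate 1 against 0.126 to 0.171, skeletal muscle 0.432 in replicate 1 against 0.205 to 0.22, and interferon response -0.0701 in replicate 2 against 0.141 to 0.18. Of the 659 unnamed probes above background, 29 passed the threshold in double mutants against controls, 12 higher and 17 lower.

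Every other way to part the 8 arrays into 4 and 4 was tried, the third group kept, giving 35 splits per comparison. The real split alone, 1 of 35, gave as many genes in each. Double mutants against controls had 251 genes against at most 0 in another split. Double mutants against 1 Mek1 allele had 45 against at most 5, and 1 Mek1 allele against controls 53 against at most 2. This met the outcome written beforehand as speaking against chance. With 35 splits, 1 of 35 is the smallest share possible, so chance is made less likely for these counts but is not excluded.

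The ciliated list was higher in double mutants by a median of 1.04. A larger share of epithelium would raise general epithelial genes alike, but 16 of them, Cdh1 and Krt8 among them, had a median of 0.17 (quartiles 0.0944 to 0.276), which argues against it as the whole cause. These genes report epithelium as a whole, so the share of airway within it was not tested. Older double mutant embryos would have less embryonic globin, whereas the 3 measured embryonic globin genes had a median of 0.774, all above 0 though none past the threshold. With 1 Mek1 allele these 3 genes also lay above controls, by 0.36, 0.37 and 0.61, where the ciliated list had a median of -0.02. They report red cells, whose share of the tissue was not measured, so an older stage is not excluded. With array brightness as a covariate the list kept adjusted p = 0.00349, though without it the call was lost at adjusted p = 0.224 with an estimated correlation. A change in ciliated cells or their genes after loss of MEK2 in every cell and of MEK1 in recombined mesenchyme stays as a hypothesis, which counts of ciliated cells in sections would test, and the smaller medians of the secretory and hypoxia lists, 0.28 and 0.33, are not separated from the epithelial share by this test.

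The 36 genes changed alike in both mutant groups lay unevenly: 9 on chromosome 13, where 1.26 would be expected (Fisher's exact test, adjusted p = 0.000144), and 7 on chromosome 6, where 1.86 would be (adjusted p = 0.0528). Of them 27.8% had another of the set within 5 tested genes, against an upper limit of 16.7% in random sets (permutation p = 4e-04), but 4 of these 10 genes were histone genes and a pair were Zfp genes; with 1 gene kept from each run of relatives the share was 12.5%, equal to the upper limit of its random sets (permutation p = 0.106), so related families may carry the neighbour excess. The chromosome counts did not go away with them: 5 of 32 genes lay on chromosome 13 (1.12 expected, unadjusted p = 0.00472) and 7 on chromosome 6 (1.65 expected, unadjusted p = 0.00102). Segments of another ancestry carried with the mutant alleles were a candidate explanation. Map2k2 lies on chromosome 10, where 1 of the 36, Map2k2 itself, lay and 1.75 would be expected. A segment around Map2k2 therefore does not account for the genes on chromosomes 13 and 6. Both mutant groups also carried floxed Map2k1, which lies on chromosome 9, and a segment around it was not tested. There 2 of the 36 lay, where 2.11 would be expected, and they were neighbours. Ooep rose by 1.73 in double mutants and 0.98 with 1 Mek1 allele, and Cd109 by 0.74 and 0.83. Such a segment and segments elsewhere in the genome cannot be judged, since the labels give 1 strain for all groups and no genotypes were read. For array brightness as a covariate, the outcome written beforehand as speaking for it was met: 6 of the 36 stayed past the threshold in both, with 21 kept in double mutants and 6 with 1 Mek1 allele. That reading was weakened only after the folds were looked at, since the median size was 0.754 before and 0.773 after in double mutants and 0.835 and 0.780 with 1 Mek1 allele, while the median SE grew from 0.127 to 0.144 and to 0.169, so brightness stays open.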

How the results depend on the processing

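The brightness and background covariates and leaving out the 2 brightest arrays were chosen after seeing the data. No named gene or list past its threshold changed sign. Counts are labelled A for double mutant against control, B for double mutant against 1 Mek1 allele, C for 1 Mek1 allele against control and D for genes alike in both mutants, in that order; as reported they are 251, 45, 53 and 36, and where fewer are given the rest stayed within 1.5 times. They were 432, 68, 206 and 97 with the authors' values, 407, 75, 224 and 95 with a trended robust variance, 591, 29, 103 and 60 with array weights, 10, 8, 5 and 3 without the 2 brightest arrays (fewer controls), and 56, 2 and 11 at adjusted p under 0.01. Without background correction A, C and D were 436, 244 and 110; with a brightness covariate 77, 10 and 8; with a background covariate 88, 11 and 9. With offset 50 B, C and D were 80, 121 and 62, and with only the arrays compared 1, 23 and 19. With detection on all arrays C and D were 105 and 56, and with every probe 97 and 59. The share of calls that were higher turned in B and C: in C from 47.2% to 80% with a brightness covariate, and in B from 75.6% to 33.3% of 3 genes without double mutant replicate 4 and to 0% of 1 gene with only the arrays compared. Requiring 1.5-fold gave 152 for A. For B, no filter gave 7, upper-quartile scaling 23 and Y-linked signal 2.

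The replicate numbers do not pair the samples: same-numbered residuals correlated between -0.23 and 0.178, over 0.1 in 3 of 12 pairs, and 4 of 24 best matches shared a number. A replicate block gave 146, 3, 20 and 17 genes, with 70% of C higher.

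Leaving out single arrays gave 109 to 287, 2 to 43, 15 to 60 and 13 to 38 genes, and 2 to 8, 5 to 10 and 0 to 2 lists. Lists for double mutants against controls, 4 as reported, were 0 with an estimated correlation, 2 with detection on all arrays, 7 with fry, with no filter or with offset 50, and 8 with the authors' values, a trended variance or no background correction. With detection on all arrays the ciliated list and the secretory and basal list had fewer than 5 measured members and were not tested. Against 1 Mek1 allele the estimated correlation gave 0 in place of 6, and upper-quartile scaling gave 1 in place of 0 for 1 Mek1 allele against controls. The correlation of the mutant effects, 0.644, was 0.587 to 0.696 with single arrays left out, 0.39 with controls split, 0.682 with the authors' values, 0.685 without background correction or with a background covariate, 0.601 without a filter and 0.678 without the brightest arrays. Apart from the counts that fewer arrays or stricter thresholds lower by construction, the cause was not tested. The chip of each array is not given in the files used here, so a chip block was not run. Dim probes limit the rest: 11967 probes were above background on 0 arrays.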

Other observations

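The test of spread in this part was chosen only after the values were seen. Several of the genes that changed alike in both mutant groups were not named in the comparisons, and they were picked here after their values were seen. Anxa4 rose by 0.58 in double mutants and 0.65 with 1 Mek1 allele, and Apoe by 0.67 and 0.78. Gpr27, above background on 0 control arrays, was at least 1.20-fold and 1.32-fold higher. Among the 15 that fell, Esco2, which acts in sister chromatid cohesion, fell by 0.64 and 0.71, the condensin gene Ncapd2 by 0.77 and 0.69, and Zfpm2, a GATA cofactor, by 0.52 and 0.65. The histone genes H2bc7, H2bc9 and H2bc11 rose by 0.63, 0.58 and 0.48 in double mutants, and probes of such similar genes may not tell them apart.

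Itgb3bp and Cdkal1 were spread widely in the mutant groups and tightly in controls. Itgb3bp ran from 9.73 to 9.94 in controls, and was 8.72, 6.86, 8.45 and 7.01 with 1 Mek1 allele and 7.19, 8.56, 7.13 and 6.99 in double mutants. Over all 36 genes changed alike, the mutant groups' SD was a median 1.16 times that of controls, against 1.17 in random sets of like brightness (permutation p = 0.546), so the set as a whole did not show a wider spread than these sets. Segments of another ancestry still segregating among the mutant embryos could widen it, but these genes were chosen by a test that favours a small spread and the random sets were not, so the value excludes nothing and such segments stay open.

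The Y-linked gene Eif2s3y was 7.48 in control replicate 3, 6.97 in 1 Mek1 allele replicate 2 and 7.16 and 7.22 in double mutant replicates 2 and 4, and between 4.28 and 5.10 on the other 8 arrays.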
